A study of Mus musculus with 24 samples.

How the data were processed

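Per the labels and the submitters' processing notes, mRNA was selected with oligo-dT from frozen liver, sequenced as strand-specific single reads of 50 bases, aligned with HISAT2 to GRCm38 and quantified per gene with StringTie, with no versions given. The deposited coverage values are the mean read coverage per base of each gene's exons as the authors' StringTie run wrote it, with no scaling for depth. The deposited FPKM values are coverage scaled for depth by the authors' StringTie run, but the ratio of coverage to FPKM was not the same for all genes. The deposited TPM values were scaled by the authors' StringTie run so that they sum to 1000000 per library over all listed genes. The largest ratio of coverage to FPKM in a library, nearly reached by 33.9% to 36.1% of the genes compared, gave its mapped gigabases. These were turned into reads of 50 bases. No read counts were in the files, so counting error could not be computed for single values.

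The files listed 43629 gene identifiers, and entries with the same identifier in a library were summed. TPM were scaled by median-of-ratios factors over the 13270 genes above 0 in all 24 libraries, which averaged 0.968 ± 0.105 (SD, n = 12) in young and 1.04 ± 0.107 in old. Scaled TPM are the values printed. Genes with a mean of at least 1 TPM over the 24 libraries were kept, and log2(scaled TPM + 0.5) was fitted with limma 3.58.1 (R 4.3.3, empirical Bayes with an intensity trend). A model with the 12 age and time groups (12 residual degrees of freedom) gave the age difference over the day, the age difference at each time and its variation over times. A model with an intercept, a cosine and a sine of 24 h per age (18 residual degrees of freedom) gave rhythms, where amplitude means the log2 difference between the fitted peak and trough. The tests were F tests of cosine and sine in young, in old, on the mean of both ages and on the difference between ages. The threshold was a Benjamini-Hochberg adjusted p under 0.05 over the genes tested. Python 3.11.15, pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9 read the tables and drew the plots.

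Tests, gene lists, the rule for named genes and most alternatives were chosen before the data were examined. 48 lists of pathway genes and cell type markers were fixed, and 40 had at least 3 tested genes. Lists with fewer tested genes were B cells and adipocytes (2 each), hepatocyte tumour and fetal genes (2), dendritic cells, platelets and gallbladder or gut epithelium (1 each), and NK cells and mesothelium (0 each), and no list test was run for these. Of the list entries, 697 matched by name in the files, 3 by a GENCODE M21 symbol and 4 by a RefSeq synonym, and 2 (Iglc1 and Iglc3) could not be matched. Lists were compared with limma's camera at a preset correlation between genes of 0.01, with an estimated correlation as the alternative, adjusted over the 40 lists. Shares of rhythmic genes were compared with all other tested genes by Fisher's exact test. The planned Fisher test of rhythm-difference genes at the adjusted threshold had 0 genes to work on by limma, against 429 at an unadjusted p under 0.05, so it was run at that level. Rhythms of list means were tested with 100000 permutations of the times within an age, and age differences of list means with an exact two-sided permutation of ages within times (46656 arrangements, since each time has 4 libraries to share between the ages).

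Genes were named by rule. For age, these were the 10 with the largest log2 difference in each direction past the threshold with at least 5 TPM in the higher age. For rhythm, they were the 10 with the largest mean amplitude past the threshold in both ages with at least 5 TPM, and every measured core clock gene, though some single genes are not reported here. For rhythm differences, they were the 10 with the smallest p among genes with the lower and among genes with the higher amplitude in old. For single times the largest rise and fall were named, and for lists up to 4 members with the smallest p. Predicted genes and clone names were counted but not named, except where said. Npas2 was below the filter and was not tested.

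The steps were tested on simulated data with 12110 genes and 50 planted changes per size. Age differences of log2 0.5, 1, 1.5 and 2 were recovered in 52%, 88%, 90% and 96% of the planted genes, and rhythms in young of those sizes in 12%, 54%, 82% and 90%. Rhythm differences were recovered in 2%, 12%, 46% and 70%, so a change of rhythm in a single gene had to be large to be called. False calls were 8 of 171 for age, 13 of 246 for young rhythms, 3 of 117 for old rhythms and 3 of 68 for rhythm differences. The simulated noise was drawn independently for each gene and library. In the data, deviations from group means correlated over 0.1 in 52 of 66 pairs of groups, so these rates may not hold there.

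Alternatives were the deposited TPM and FPKM without scaling, quantile normalization, pseudocounts of 0.1 and 1, no filter and a filter at 5 TPM, library weights, robust empirical Bayes, a replicate block, a 12 h harmonic, an F test over times, a fit per age, an added 1.5-fold threshold and each library left out in turn. Added after seeing the data were leaving out ZT10, leaving out a pair of libraries, leaving out all libraries of a replicate number (with a model of age plus time for the age difference, since each group then holds 1 library), and the exact permutation of list means.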

Results

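Liver mRNA was sequenced from wild-type C57BL/6 mice, an inbred laboratory strain, at 2 ages: young (about 4 months) and old (about 19 months). Livers were taken at 6 zeitgeber times (ZT, hours after lights on): ZT2, ZT6, ZT10, ZT14, ZT18 and ZT22. Each age and time had 2 replicate libraries, which gave 24 libraries, 12 per age. The labels do not say whether replicates are separate animals, what the replicate number marks or which sex was used, so each p measures the spread between these samples. The largest ratio of the deposited coverage to the deposited FPKM put the mapped depth at 0.435 to 0.683 gigabases per library. Counted in reads of 50 bases, that equals 8.70 to 13.7 M per library, with a median of 10.5 M. Young libraries held 9.68 to 13.7 M such reads and old libraries 8.70 to 12.3 M. Between 15989 and 16690 genes were above 0 in a library, and 12261 genes with a mean of at least 1 TPM were tested.

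Markers of sex and of the main cell type were alike at both ages. Albumin (Alb), the main plasma protein made by hepatocytes, was at 69810.3 scaled TPM in young and 64698.6 in old, with a log2 difference of -0.11 and an adjusted p of 0.817. Ddx3y, a Y-linked gene, was at 41.2 in young and 39.0 in old, while Xist, the RNA of the inactive X chromosome, stayed at or below 0.0089 in every library. Profiles of the 12 replicate pairs correlated at 0.940 or more across genes, with a median of 0.960, against a median of 0.949 for other pairs. 2 libraries of old ZT14 held a low share of mitochondrially encoded RNA, 3.42% in replicate 1 and 8.74% in replicate 2, against 10.7% to 17.1% elsewhere. Replicate 2 of young ZT18 held digestive enzyme mRNAs of pancreatic acinar cells, with Ctrb1 (chymotrypsinogen B) at 724, Cela2a (an elastase) at 609.9 and Amy2a5 (pancreatic amylase) at 604 scaled TPM. Leaving both young ZT18 replicate 2 and old ZT14 replicate 1 out, a choice made after seeing the data, gave 126 higher and 54 lower genes in the comparison of ages that follows.

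The first comparison asked which transcripts differ in level between old and young liver, averaged over the day. Antibody transcripts made up 6 of the 10 named genes that rose most. Igkv5-39, a kappa light chain variable segment (chromosome 6, 69900424 to 69900710, GRCm38), went from 0.212 ± 0.340 scaled TPM in young to 7.81 ± 3.41 in old (mean ± SD, n = 12 libraries per age), a log2 difference of 3.54 (SE 0.248, adjusted p = 1.75e-06). Igkc, the kappa constant region (chromosome 6, 70726435 to 70726757), went from 21.2 ± 9.498 to 143 ± 93.6, and Ighm, the constant region of IgM (chromosome 12, 113418558 to 113422730), from 6.70 ± 2.22 to 55.0 ± 47.7. Ighg2c and Ighg2b, constant regions of IgG, rose by log2 2.67 and 2.25, and Iglv1, a lambda variable segment, by 2.45. Lcn2, the siderophore-binding protein lipocalin-2 (chromosome 2, 32384633 to 32388252), rose from 5.49 ± 2.59 to 112 ± 192 (log2 2.66, SE 0.336, adjusted p = 0.00038). Cxcl1, a chemokine that attracts neutrophils, rose from 5.28 ± 1.998 to 39.9 ± 44.3 (log2 2.25, adjusted p = 0.000769). S100a8, a calcium-binding protein abundant in neutrophils, rose from 4.59 ± 4.79 to 24.7 ± 21.1 (log2 2.69, SE 0.618, adjusted p = 0.0359). Cyp2b9, a cytochrome P450 usually higher in female mouse liver, rose from 0.907 ± 1.45 to 8.44 ± 6.78 (log2 2.74, SE 0.403, adjusted p = 0.00142). All 10 were higher in old at 6 of 6 times by the sign of the fitted difference, with 2 libraries per age at each. Some of these differences were small against their SE: at ZT18, Lcn2 was at 6.87 in young and 6.94 in old (log2 0.32, SE 0.822).

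Cytochromes P450 made up 4 of the 10 named genes that fell most. Cyp3a16 (chromosome 5, 145436309 to 145469723), of the drug-metabolising 3A family, went from 63.2 ± 39.95 scaled TPM in young to 4.37 ± 15.1 in old (adjusted p = 0.0209). It was listed at 0 in 11 of 12 old and 3 of 12 young libraries and shares sequence with Cyp3a11, so its fitted log2 difference of -4.98 (SE 1.05) is no bound. The fatty acid omega-hydroxylases Cyp4a10 and Cyp4a31 fell with age. Cyp4a10 (chromosome 4, 115518264 to 115533649) went from 160.4 ± 51.0 to 66.2 ± 28.9 (log2 -1.32, SE 0.181, adjusted p = 0.000823) and Cyp4a31 from 23.3 ± 9.35 to 9.10 ± 6.29 (log2 -1.42, adjusted p = 0.00165). Cyp4a12b, of the same family and usually higher in male liver, went from 107 ± 21.8 to 59.3 ± 11.1 (log2 -0.84, SE 0.104, adjusted p = 0.000326). Tceal8, a transcription elongation factor-like gene on chromosome X, went from 11.03 ± 2.97 to 4.12 ± 0.975 (log2 -1.30, SE 0.168, adjusted p = 0.000446). Gpr110 (an adhesion receptor), Slc39a4 (a zinc importer) and Fkbp11 (a prolyl isomerase of the secretory pathway) fell by log2 1.05, 1.003 and 0.92. These 8 genes were lower in old at 6 of 6 times. Nucb2 (nucleobindin 2) fell by log2 0.87 and Usp18 (a protease that removes ISG15) by log2 0.83, each lower at 5 of 6 times.

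**Figure D1:**
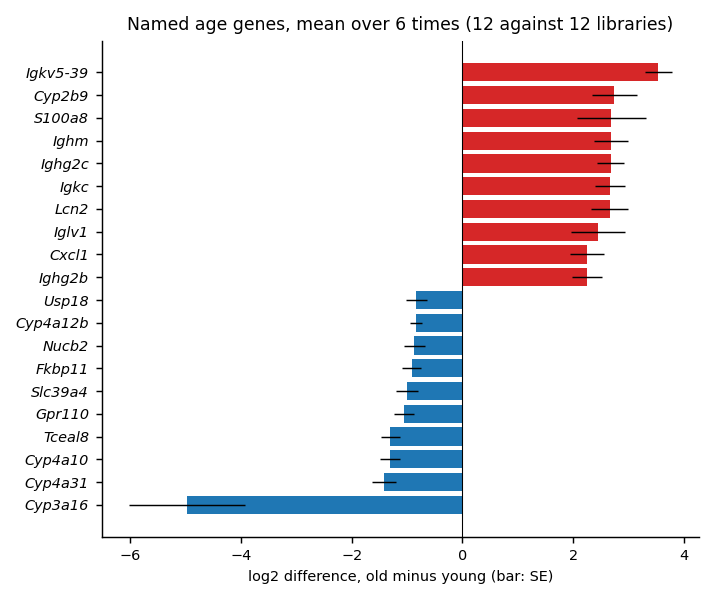
Bars give the log2 difference, old minus young and averaged over 6 times, for the 10 named genes with the largest rise and the 10 with the largest fall, and whiskers give the SE from the fitted model (12 libraries per age). Values run from 3.54 for Igkv5-39 to -4.98 for Cyp3a16.

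Over all 12261 genes, 140 were higher and 61 lower in old at an adjusted p under 0.05, so 69.7% of the 201 were higher, and the median log2 difference of all tested genes was -0.01. With the deposited TPM unscaled the split was 225 higher and 38 lower, or 85.6% higher, with a median shift of 0.09, and with the deposited FPKM it was 222 and 49, or 81.9%. Leaving out ZT10 gave 70 higher and 46 lower, and a filter at 5 TPM gave 68 higher and 58.6% higher among the genes past the threshold. S100a8, Nucb2 and Usp18 lost their calls in 19, 18 and 17 of the 24 fits that each left out 1 library.

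Groups of genes were then compared through lists fixed beforehand. Among the 9 tested plasma cell and immunoglobulin transcripts, 8 rose, both over all genes and adjusted over the list alone, with a median log2 difference of 2.14 (camera adjusted p = 7.6e-19). Jchain, which joins polymeric antibodies, went from 4.09 to 17.6 scaled TPM (log2 1.94, adjusted p = 0.000903). Sdc1 (syndecan-1), which hepatocytes also express, was the exception at 91.7 in young and 88.5 in old. The list kept its call with an estimated correlation (adjusted p = 0.0211), as did acute phase proteins and neutrophils and none of the other 37 lists. Of 20 acute phase transcripts, those of plasma proteins made by an inflamed liver, 5 rose over all genes and 14 adjusted over the list alone, with a median log2 difference of 0.48 (camera adjusted p = 6.21e-18, and adjusted p = 0.0269 with an estimated correlation). Orm3 (an orosomucoid) went from 2.04 ± 1.03 to 10.5 ± 7.68 (adjusted p = 0.000532), Saa4 (a serum amyloid A) from 169.5 ± 46.0 to 235 ± 51.9 (log2 0.48, adjusted p = 0.00625) and Hp (haptoglobin) from 2346.5 ± 359.7 to 3929.2 ± 1320.0 (log2 0.68, adjusted p = 0.00669). Libraries differed widely within old liver: Saa2 (serum amyloid A2) reached 8279.1 and 1082.5 in the 2 libraries of old ZT10, while the mean over old liver was 1048.7 ± 2340.9. All 3 tested neutrophil transcripts were higher in old, 2 of them past the threshold over all genes and 3 adjusted over the list alone (median log2 1.45, camera adjusted p = 2.63e-05, and adjusted p = 0.0211 with an estimated correlation). S100a9, the partner of S100a8, went from 6.33 ± 4.20 to 22.6 ± 20.1 (log2 1.45, adjusted p = 0.00808).

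Macrophage transcripts were higher in old too. Of 16 Kupffer cell and macrophage genes, 2 rose over all genes and 5 adjusted over the list alone (median log2 0.21, camera adjusted p = 6.34e-07). That call was lost with an estimated correlation, at an adjusted p of 0.202. Marco, a scavenger receptor (chromosome 1, 120474538 to 120505024), went from 6.28 ± 2.47 to 28.7 ± 14.2 scaled TPM (log2 2.01, SE 0.167, adjusted p = 1.3e-05), and Mpeg1, a pore-forming protein of macrophages, from 35.7 ± 6.36 to 55.7 ± 24.3 (log2 0.55, adjusted p = 0.0107). Cxcl1 was 1 of 14 chemokines and cytokines past the threshold over all genes, and 6 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.000408, and adjusted p = 0.170 with an estimated correlation). All 7 tested genes of MHC class II antigen presentation were higher in old (median log2 0.31), with none past the limma threshold over all genes and 4 adjusted over the list alone. H2-Ab1, a class II chain, was at 29.6 in young and 37.5 in old (camera adjusted p of the list = 0.00048, and adjusted p = 0.257 with an estimated correlation). The 7 markers of monocyte-derived macrophages were also all higher, with 2 past the threshold adjusted over the list alone (median log2 0.31, camera adjusted p = 0.00663, and adjusted p = 0.184 with an estimated correlation). Of 14 glucocorticoid targets, Lcn2 rose over all genes and 4 adjusted over the list alone (camera adjusted p = 0.000926, and adjusted p = 0.202 with an estimated correlation). Among 16 genes of iron, copper and zinc handling, Slc39a14, a metal importer, went from 47.7 to 70.9 (log2 0.56, adjusted p = 0.00806), and 5 rose and 2 fell adjusted over the list alone (camera adjusted p = 0.0450, and adjusted p = 0.172 with an estimated correlation). Sox9, a bile duct transcription factor, was the 1 of 3 cholangiocyte genes that rose (1.57 to 2.31, adjusted p = 0.0305), with camera adjusted p = 0.0332 for the list, and adjusted p = 0.170 with an estimated correlation. The 7 senescence-associated genes had 0 past the limma threshold over all genes and 2 adjusted over the list alone (median log2 0.20, camera adjusted p = 0.0464, and adjusted p = 0.174 with an estimated correlation).

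Male-biased liver transcripts were lower in old, with 3 of 15 past the threshold over all genes, and 9 lower and 1 higher adjusted over the list alone (median log2 -0.37, camera adjusted p = 4.12e-06). The adjusted p was 0.0860 with an estimated correlation. Cyp4a12a, an omega-hydroxylase, fell from 221 ± 41.2 to 132 ± 24.5 scaled TPM (log2 -0.74, adjusted p = 0.00038) and Slco1a1, an organic anion transporter, from 367 ± 35.2 to 279 ± 68.4 (log2 -0.43, adjusted p = 0.0218). All 13 mitochondrially encoded transcripts were lower in old, with a median log2 difference of -0.51 and 0 past the limma threshold (camera adjusted p = 1.82e-06, and adjusted p = 0.202 with an estimated correlation). mt-Cytb (cytochrome b) was at 18499.6 ± 4774.3 in young and 13901.8 ± 5357.5 in old (log2 -0.54, SE 0.183, adjusted p = 0.206). The old ZT14 libraries with 3.42% and 8.74% mitochondrial RNA move with this list. Of 25 nuclear genes of oxidative phosphorylation, 24 were lower, by a median of log2 -0.16, with 0 past the limma threshold over all genes and 1 adjusted over the list alone (camera adjusted p = 5.5e-06, and adjusted p = 0.251 with an estimated correlation). The mean of that list, -0.163, shrank to -0.053 under the alternative that moved it most. An exact permutation of ages on its mean gave adjusted p = 0.0796. Usp18 was 1 of 21 interferon-response genes to fall over all genes, and 2 fell adjusted over the list alone (median log2 -0.26, camera adjusted p = 0.00138, and adjusted p = 0.494 with an estimated correlation).

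**Figure D2:**
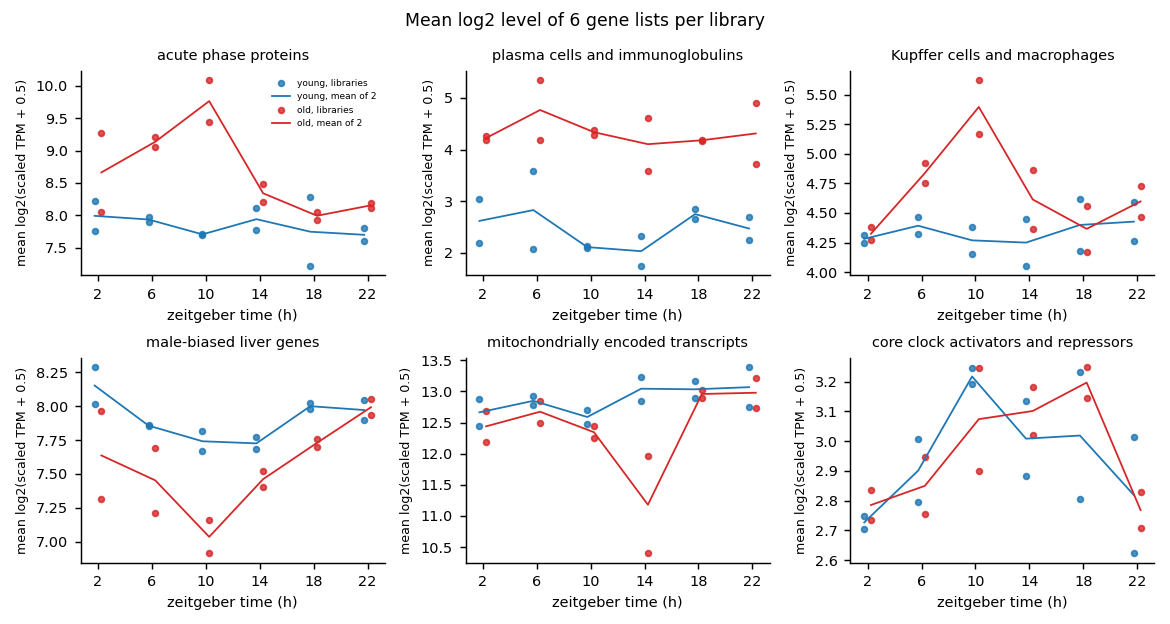
Each dot is the mean of log2(scaled TPM + 0.5) over a list in 1 library, with 12 young and 12 old libraries per list, for 6 of the fixed lists. Plasma cell transcripts differed by a mean of 1.86 between ages and acute phase transcripts by 0.84, whereas mitochondrially encoded transcripts differed by -0.45, with the lowest value in old ZT14.

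3 further lists passed camera with few or no single genes behind them. Of 20 cholesterol synthesis genes, 19 were higher in old by a median of log2 0.16 and 0 passed the limma threshold (camera adjusted p = 0.00102, and adjusted p = 0.523 with an estimated correlation). The unfolded protein response had 15 of 20 genes lower, with a median of log2 -0.14 and 0 past the limma threshold (camera adjusted p = 0.0363, and adjusted p = 0.448 with an estimated correlation), but its mean was 0.03 with the deposited TPM unscaled. Fatty acid oxidation and PPARalpha targets went both ways. Acot1 (an acyl-CoA thioesterase) fell by log2 0.74 and Cyp4a10 fell as above, whereas Cidec (a lipid droplet protein) rose from 0.791 to 3.16 and Cd36 (a fatty acid transporter) from 21.7 to 32.2. In that list 2 of 22 rose and 2 fell over all genes, and 2 rose and 5 fell adjusted over the list alone (camera adjusted p = 0.0450, and adjusted p = 0.782 with an estimated correlation). In all, 18 of 40 lists passed camera, 3 of them with an estimated correlation, and 10 by an exact permutation of age labels within times on each list's mean, a test added after seeing the data. Plasma cells and immunoglobulins (exact permutation adjusted p = 0.00172), male-biased genes (0.00514), acute phase proteins and neutrophils (both 0.00900) and Kupffer cells (0.0415) were among the 10. Senescence-associated genes (exact permutation adjusted p = 0.0127), cholangiocytes (0.01315), chemokines and cytokines (0.0332) and glucocorticoid targets (0.0332) were as well. So were female-biased genes (exact permutation adjusted p = 0.0332), whose mean of -0.76 includes the log2 difference of -4.98 for Cyp3a16, a value that is no bound. Some lists share members, so the 18 and the 10 are not all separate results. Lcn2 is in the acute phase and glucocorticoid lists, and Mt1 and Mt2 are in the glucocorticoid and metal handling lists. Ccl2 is in the chemokine and senescence lists. Without 1 library, the camera call was lost in 16 of 24 fits for senescence-associated genes, 14 for metal handling, 12 for fatty acid oxidation and 9 each for the unfolded protein response and cholangiocytes. The mean of fatty acid oxidation genes went from -0.12 to -0.07 without old ZT6 replicate 1 and to -0.08 without old ZT18 replicate 1. That of the unfolded protein response went from -0.07 to -0.04 without young ZT6 replicate 2 or old ZT14 replicate 2, and that of interferon-response genes from -0.23 to -0.14 without young ZT10 replicate 1. With the deposited TPM or FPKM the calls of senescence-associated, metal handling and cholangiocyte genes were lost, and with quantile normalization those of senescence-associated genes, fatty acid oxidation and the unfolded protein response.

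Other lists did not pass camera. Among 17 drug-metabolising cytochromes P450 and regulators, Cyp3a11, the main drug-metabolising 3A enzyme of mouse liver, fell from 3500.5 ± 546.8 to 2097.7 ± 536.7 scaled TPM (log2 -0.76, SE 0.119, adjusted p = 0.00246) and Cyp2b9 rose, with 2 up and 2 down adjusted over the list alone. The median of that list was -0.01 and its mean 0.08 (camera adjusted p = 0.712). Gstp1, a glutathione transferase annotated under 2 overlapping gene identifiers, fell from 1532.8 to 1011.8 (log2 -0.61, adjusted p = 0.00669) as 1 of 18 phase II genes, with 2 lower adjusted over the list alone (camera adjusted p = 0.144). Female-biased genes went both ways: Cyp17a1, a steroid hydroxylase, rose from 6.95 to 13.3 (log2 0.87, adjusted p = 0.0386) with Cyp2b9, and Cyp3a16 fell (2 rose and 3 fell adjusted over the list alone, camera adjusted p = 0.953). Mup12 rose from 7.01 to 13.4 (log2 0.92, adjusted p = 0.0143) among 13 major urinary proteins, near-identical pheromone carriers whose reads are shared, while 1 rose and 3 fell adjusted over the list alone (camera adjusted p = 0.491). Of 15 bile acid genes, 1 fell over all genes, and 1 rose and 1 fell adjusted over the list alone (camera adjusted p = 0.753). In the growth hormone and IGF axis 2 of 14 rose adjusted over the list alone (camera adjusted p = 0.627), and 1 each of 23 complement and coagulation genes (camera adjusted p = 0.252) and 13 endothelial genes (camera adjusted p = 0.646) fell. Camera adjusted p was 0.0668 for fatty acid synthesis, with 16 of 18 genes higher, 0.139 for pancreatic acinar genes, 0.252 for the cell cycle and 0.336 for cytosolic ribosomal proteins. Heat shock, urea cycle, T cell and clock output lists had camera adjusted p = 0.648. The core clock (0.735), erythroid genes (0.653), hepatocytes (0.786), gluconeogenesis and stellate cells (both 0.953) and sex-linked genes (0.998) had higher camera adjusted p values.

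Age was also compared at each time, with 2 libraries per age. ZT10 had 65 genes past the threshold, 55 higher and 10 lower in old. Saa2 showed the largest rise, from 32.7 ± 2.28 to 4680.8 ± 5088.8 scaled TPM (n = 2 per age, log2 6.50, SE 1.38, limma adjusted p = 0.0492), and Acot1 the largest fall, from 24.8 ± 6.97 to 8.15 ± 1.37 (log2 -1.53, SE 0.294, limma adjusted p = 0.0310). Lcn2, named after its values were seen, went from 4.31 to 461 ± 299 at ZT10 (log2 6.46, limma adjusted p = 0.00225). At ZT14 the count was 4 higher and 1 lower, led by Igkv5-39, which was listed at 0 in both young libraries and at 7.62 ± 3.45 in old (limma adjusted p = 0.0273). The other 4, named after their values were seen, were Marco (5.35 to 34.9), Rab11b, a small GTPase of recycling endosomes (5.88 to 20.1), 2610305D13Rik (0.512 to 4.02) and Gm11512 (199.5 to 78.0). ZT18 had 2 higher and 1 lower: Igkv5-39 (0.211 to 10.5 ± 4.76, limma adjusted p = 0.0379) and, named after their values were seen, 2610305D13Rik (0.752 to 5.67) and Gm15832 (21.7 ± 5.07 to 0.793). 2610305D13Rik was the 1 gene past the threshold at ZT22 (0.450 to 4.43). ZT2 and ZT6 had 0 genes past the limma threshold, with 492 and 495 at an unadjusted p under 0.05, against 971, 964, 569 and 373 at ZT10, ZT14, ZT18 and ZT22. Of 12261 genes, only the ZT10 and ZT14 counts are above the share of 0.05 that chance alone gives if libraries vary independently.

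The single-time counts moved with single libraries. The ZT10 count was 10 and 6 without either young ZT10 library and 30 and 25 without either old one. The ZT14 count was 53 without old ZT14 replicate 2 and 0 without replicate 1, the ZT18 count was 36 without young ZT18 replicate 1, and the ZT6 count was 27 without old ZT6 replicate 1. The call of Saa2 was lost in 22 of 24 such fits, that of Acot1 in 4, and those of Igkv5-39 in 6 (ZT14) and 15 (ZT18). A test of whether the age difference varied over the 6 times gave an unadjusted p under 0.05 for 442 of 12261 genes. That share is below the 0.05 that chance alone gives if libraries vary independently. By limma 2 genes passed the threshold. Both, named after their values were seen, are predicted genes present in some groups and near 0 in others: Gm7729 (limma adjusted p = 0.0122) and Gm15832 (limma adjusted p = 0.0153). That count was 36 without young ZT18 replicate 1 and 0 without old ZT18 replicate 2.

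A further comparison asked how daily rhythms of liver transcripts differ between the ages, through a 24 h cosine fitted to each gene. The core clock cycled at both ages. Arntl (BMAL1, the clock activator, chromosome 7, 113207465 to 113314122) had a log2 peak-to-trough difference of 4.90 (SE 0.407) with a peak at ZT23.0 in young and 5.002 at ZT22.6 in old. Nr1d1 (the repressor REV-ERBalpha, chromosome 11, 98767932 to 98775333) cycled by 5.93 (SE 0.464) with a peak at ZT7.56 in young and by 5.74 at ZT7.21 in old. Among the repressors of the negative limb, Per2 went from 3.48 (SE 0.242) with a peak at ZT15.4 in young to 3.10 at ZT15.0 in old, and Cry1 from 2.61 (SE 0.201) at ZT20.2 to 3.19 at ZT19.7. Per1 (2.96 and 3.04), Per3 (3.09 and 3.15), Nr1d2 (3.41 and 3.07) and Clock (1.18 and 1.54) were rhythmic at both ages as well. Of 14 tested core clock genes, 9 passed the rhythm test in both ages, with adjusted p = 0.00470 for Clock in young. Cry2 (0.84 and 0.52, adjusted p = 0.103 and 0.435), Rora (0.51 and 0.53), Csnk1d and Csnk1e were among those that passed in neither. Cry2 passed on the mean of both ages (adjusted p = 0.0327), a call lost in 10 of 24 fits without 1 library.

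**Figure D3:**
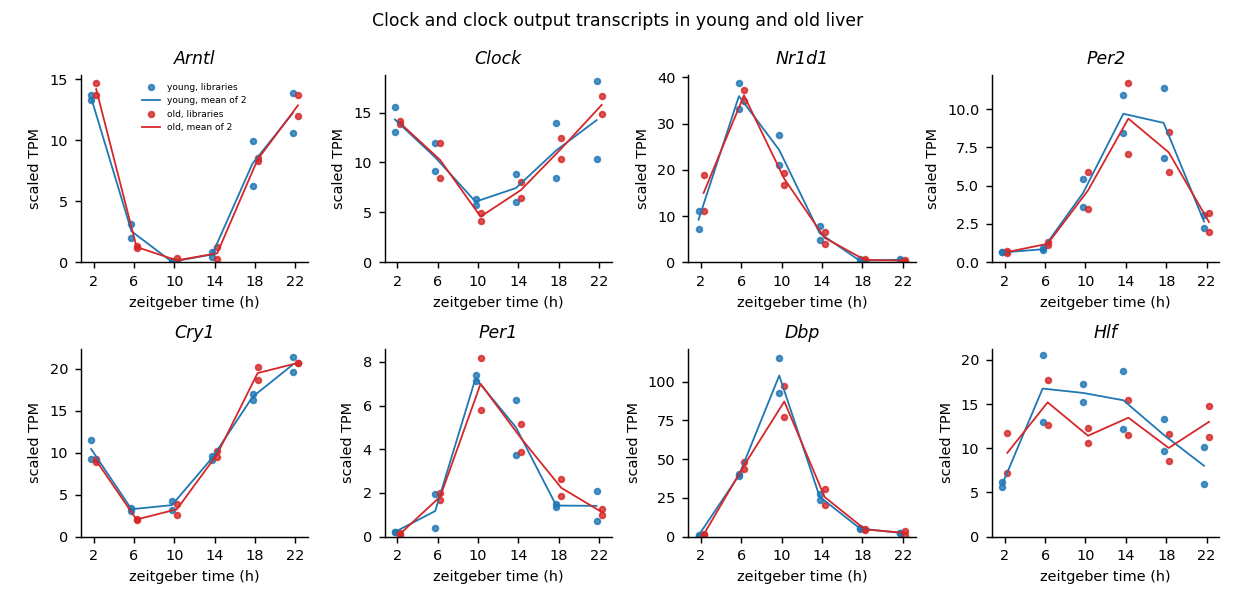
Scaled TPM against zeitgeber time in hours for 8 clock and clock output genes, where each dot is 1 library, blue for young and red for old, and each line joins the means of 2 libraries. The curves of Arntl and Nr1d1 of young and old lie close together, whereas Hlf had a log2 peak-to-trough difference of 1.35 in young and 0.25 in old.

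All 9 rhythmic core clock genes had their fitted peak earlier in old, by 0.136 h (Per1) to 0.569 h (Clock), with a median difference of -0.347 h. In an exact two-sided permutation of ages within times, chosen after seeing the data, that median had p = 0.0927. All 9 shifted the same way, in either direction, in a share of 0.0144 of the 46656 arrangements. Amplitude was lower in old for 3 of them and higher for 6, with a median log2 difference of 0.06. None passed a limma test of a rhythm difference, over all genes or adjusted over the list alone, where the smallest adjusted p was 0.832. Of 14 clock outputs, all 14 were rhythmic in young and 12 in old. Dbp, a transcription factor driven by the clock (chromosome 7, 45705088 to 45710155), cycled by log2 5.94 (SE 0.666) with a peak at ZT10.6 in young and by 5.76 at ZT10.3 in old. Its relative Tef cycled by 3.10 and 2.83, and Ciart, a clock repressor, by 4.90 and 4.09. Nampt, an enzyme of NAD synthesis, cycled by 1.84 and 1.89, and Wee1, a cell cycle kinase, by 2.74 and 3.03. Hlf, another relative of Dbp, passed in young (1.35, SE 0.297, adjusted p = 0.0130) and not in old (0.25, SE 0.297, adjusted p = 0.880), but the difference itself did not pass (limma adjusted p = 0.9999). Bhlhe40, a repressor, had adjusted p = 0.0521 in old.

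Among named genes with a mean of at least 5 TPM, the largest rhythms past the threshold in both ages after Dbp and Nr1d1 were those of Rgs16 and Elovl3. Rgs16, a regulator of G protein signalling, cycled by log2 5.32 (SE 0.404) with a peak at ZT8.98 in young and by 5.21 at ZT9.04 in old. Elovl3, a fatty acid elongase, cycled by 4.75 (SE 0.438) with a peak at ZT0.778 and by 5.54 at ZT23.5. Arntl came next, followed by Usp2 (a deubiquitinase, 4.54 and 4.90), Pcsk4 (a proprotein convertase, 5.01 and 4.24), Mfsd2a (a lysolipid transporter, 4.00 and 3.77), Chka (choline kinase, 3.36 and 4.41) and Alas1 (the first enzyme of heme synthesis, 3.40 and 3.48).

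Genes of metabolic and stress lists cycled too, counted here by the test on the mean of both ages. By that test, 15 of 16 heat shock genes were rhythmic (Fisher adjusted p = 1.17e-07), against 7 in young and 7 in old by themselves. Hspb1, a small heat shock protein, cycled by log2 2.78 with a peak at ZT19.2 in young and by 2.21 at ZT19.6 in old. Cholesterol synthesis had 14 rhythmic genes of 20 (Fisher adjusted p = 0.000203), among them Hmgcs1, which makes HMG-CoA (2.01 with a peak at ZT0.234, and 1.80 at ZT0.952). Fatty acid synthesis had 13 of 18 (Fisher adjusted p = 0.000203), with Thrsp, a lipogenic regulator, at 3.36 with a peak at ZT17.1 and 3.03 at ZT16.5. Gluconeogenesis and glycogen genes (10 of 14) and glucocorticoid targets (10 of 14) each had Fisher adjusted p = 0.00115. Ppp1r3b, a glycogen-targeting phosphatase subunit, cycled by 3.19 with a peak at ZT19.0 and by 2.90 at ZT19.1, and Gys2, the liver glycogen synthase, by 2.06 at ZT12.3 and 1.85 at ZT12.4. The unfolded protein response (13 of 20, Fisher adjusted p = 0.00075), bile acid genes (9 of 15, Fisher adjusted p = 0.0121) and metal handling genes (9 of 16, Fisher adjusted p = 0.0199) were enriched as well, beside the core clock (11 of 14, Fisher adjusted p = 0.000203) and its outputs (14 of 14, Fisher adjusted p = 7.92e-08). Fewer passed in young and old alone: 9 and 5 for cholesterol synthesis, 8 and 4 for gluconeogenesis, 4 and 1 for the unfolded protein response. Cytosolic ribosomal proteins had 0 rhythmic genes of 28 by limma (Fisher adjusted p = 0.00281). These Fisher tests treat genes as independent. With times permuted within an age, the mean of clock outputs passed in both ages and that of fatty acid synthesis in young. Heat shock, glucocorticoid and metal handling means passed in old. The other enriched lists passed in neither, also the core clock, whose genes peak at different times.

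Over all 12261 genes, 1316 were rhythmic in young (10.7%) and 1098 in old (8.96%) at an adjusted p under 0.05. Both ages shared 669, of which 605 peaked within 2 h of each other, with a median gap of 0.750 h. Of the 669, 340 had a lower and 329 a higher amplitude in old. A further 647 passed in young alone and 429 in old alone, of which 327 and 203 had an unadjusted p under 0.05 in the other age. A fit to each age by itself called 793 genes in young, an F test over the 6 times without a cosine 841 in young and 693 in old, and the data without ZT10 631 and 562, whereas library weights gave 2216 in young.

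**Figure D4:**
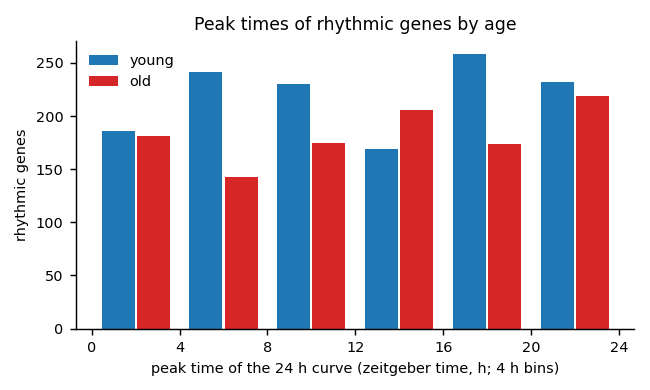
Bars give the number of rhythmic genes whose fitted peak fell in each 4 h bin of zeitgeber time, for young (1316 genes) and old (1098 genes). The bin from ZT4 to ZT8 held 241 young and 143 old genes (18.3% and 13.0% of each age's total), that from ZT12 to ZT16 held 169 and 206 (12.8% and 18.8%) and that from ZT16 to ZT20 held 258 and 174 (19.6% and 15.9%), with no test of these shares.

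The last comparison tested the difference of rhythm itself. Of 12261 genes, 429 had an unadjusted p under 0.05, a smaller share than the 0.05 that chance gives if libraries vary independently. Deviations from group means correlated over 0.1 in 52 of 66 pairs of groups. In simulated data, planted rhythm differences of log2 1 were called in 12% of genes. The share therefore does not show that rhythms are alike. By limma 0 genes passed, with a smallest adjusted p of 0.0721. The count was 3 without old ZT14 replicate 1 and 2 without old ZT2 replicate 2. The genes with the smallest p are therefore given by value. Rab11b had the smallest, with a log2 peak-to-trough difference of 1.90 (SE 0.258) in young and 0.62 in old. Next among those with the lower amplitude in old were Osbpl1a (an oxysterol-binding protein, 0.67 and 0.46), Slc25a20 (the mitochondrial carnitine carrier, 0.48 and 0.47), Ssrp1 (a histone chaperone subunit) and Shkbp1 (1.30 and 0.83). Tmem258 (1.38 and 0.92), Nnmt (nicotinamide methyltransferase, 1.48 and 1.23), Ifi47 (an interferon-induced GTPase, 1.20 and 0.42), Decr2 (a peroxisomal reductase, 0.99 and 0.42) and Nt5m (a mitochondrial nucleotidase, 0.74 and 0.24) followed. The test takes amplitude and peak time together, and the fitted peaks of these 10 genes lay between 2.59 h (Decr2) and 11.7 h (Nt5m) apart between ages, with 9.59 h for Rab11b and 6.79 h for Slc25a20. The amplitude differences of Ssrp1, Slc25a20 and Nnmt changed sign under other settings.

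Among those with the higher amplitude in old, Lcn2 had a log2 peak-to-trough difference of 0.14 (SE 0.686) in young and 5.68 (SE 0.686) in old with a peak at ZT8.20 (limma adjusted p of the difference = 0.135, and 0.0362 without old ZT14 replicate 1 or 0.0367 without old ZT2 replicate 2). Hpx (hemopexin, 0.33 and 1.19, peak at ZT8.29 in old), Marco (0.57 and 1.79, ZT9.79), Slc11a1 (a metal transporter of phagocytes, 0.48 and 1.40), Tgtp1 (an interferon-induced GTPase, 0.43 and 2.77) and Serpina3g (a serine protease inhibitor, 0.55 and 1.75) were in this group. So were Acot1 (0.32 and 1.88, ZT18.8), Srd5a1 (a steroid reductase, 0.15 and 0.81), Tmem176a (0.10 and 0.85) and Pkm (pyruvate kinase, 0.52 and 0.74). Among 20 acute phase transcripts, 2 were rhythmic in young and 13 in old, and 9 had a rhythm difference adjusted over the list alone, led by Lcn2, Hpx, Orm3 and Hp. The mean of that list cycled by log2 0.15 in young and by 1.59 in old, with a peak at ZT7.86 (permutation p = 0.860 and 0.00973, and adjusted p = 0.0512 in old over 40 lists). Its share of genes with an unadjusted p under 0.05 was 11 of 20 (Fisher adjusted p = 4.29e-10), followed by interferon-response genes (8 of 21, Fisher adjusted p = 5.74e-06), Kupffer cells (7 of 16, Fisher adjusted p = 7.09e-06) and glucocorticoid targets (Fisher adjusted p = 0.000789). Fisher's test treats genes as independent, and an exact permutation of age labels on list means gave a smallest adjusted p of 0.619.

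Over the 2935 genes rhythmic on the mean of both ages, amplitude differed between ages by a median of log2 -0.04 (permutation p = 0.59, two-sided, 100 draws with an SD of 0.0631). The median was -0.12 without young ZT22 replicate 2 and -0.11 with library weights. The peak-to-trough fold had a median of 1.70 in young and 1.64 in old, and 1628 of the 2935, or 55.5%, had the lower amplitude in old. Peak times differed by a median of 0.01 h (permutation p = 0.95, SD 0.247 h). Choosing genes on the mean of both ages disfavours those whose peaks lie far apart, since their curves partly cancel. Among genes rhythmic in young, a choice that favours young, the median amplitude difference was -0.21, and with the deposited TPM unscaled the median peak difference was 0.413 h.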

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

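The splits of the samples were planned, and the tests of the 3 patterns weighed here (acute phase transcripts, a block on chromosome 4, mitochondrial transcripts) were chosen only after the results were seen. A test of whether the age difference varied between times picked out Gm7729 (adjusted p = 0.0122) and Gm15832 (adjusted p = 0.0153). Gm7729 was at 5.83 scaled TPM in young ZT6, 4.37 in young ZT18, 5.56 in old ZT10 and 4.58 in old ZT14, with a mean of 2.37 ± 3.36 in old ZT2 and 0 in the other groups. Gm15832 was at 21.7 in young ZT18 and between 0.523 and 1.25 elsewhere. Rhythms differed between ages, adjusted over the list alone, for 9 acute phase transcripts and for 3 Kupffer cell genes (Marco, C1qb and C1qa). These counts stand against 0 genes over all genes by limma (smallest adjusted p 0.0721, 429 at an unadjusted p under 0.05), and the exact permutation of list means gave adjusted p = 0.670 for acute phase and 0.619 for Kupffer cell rhythm differences. The count was 1 each for fatty acid oxidation (Acot1), glucocorticoid targets (Lcn2), interferon response (Gbp2), chemokines and cytokines (Ccl2), senescence (Ccl2) and neutrophils (S100a9).

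Acute phase transcripts were higher in old than young. A single library does not account for the age difference, since its exact permutation p stayed at or below 0.00364 whichever of the 24 libraries was left out (highest without young ZT2 replicate 2). Neutrophils in the tissue do not account for the rise of Hp, since S100a8 and S100a9 together gained 36.4 scaled TPM, or 2.30% of the 1582.7 gained by Hp. Of the other 19 members, 7 also gained over 10 times as much as the S100 pair, and for the other 12, among them Lcn2 with a gain of 106 and Orm3 with 8.46, neutrophils cannot be told apart from a change in the liver's own cells. The daily curve of the list in old liver had a permutation p of 0.00973, or 0.0512 adjusted over 40 lists, so inflamed old animals that fell on some times by chance cannot be told apart from a daily rhythm with 2 libraries per time, and age itself stays open as an untested biological explanation.

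A block of predicted genes on chromosome 4 (146239954 to 147642513) was higher in old: 7 of 13 tested genes passed, named after their values were seen as Gm13169, Gm13166, Gm13251, Gm13248, Gm13139, Gm13152 and 2610305D13Rik. Reads of 1 source spread over near-identical copies cannot be told apart from a change of each gene. The 5 tested genes with over 50% unique 50-base words had a median log2 difference of 1.11 but went from 0.11 to 2.12, with 2 of them not past the threshold, and the other 4 called genes held at most 29.5% unique words. Substrains that differ at Nnt, which some C57BL/6 lines lack in part, are argued against by a log2 age difference of -0.0678 (SE 0.118) for Nnt. Another substrain or colony difference between the young and old mice was not tested and could give such a block, as could age.

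Mitochondrially encoded transcripts were lower in old, by 0.446 in mean log2 value. Old ZT14 replicate 1, with 3.42% mitochondrial RNA, does not account for all of it: without that library the difference was -0.315 and the exact permutation p 0.0300. Old ZT14 replicate 2, at 8.74% mitochondrial RNA, stayed in that comparison, and no test left out both old ZT14 libraries. A fall mainly at ZT14 is therefore not excluded. More nuclear RNA in old libraries is argued against by Malat1, an abundant nuclear RNA, with a log2 difference of -0.26 (SE 0.247). The exact p exceeded 0.05 in 4 of the 24 sets without 1 library, up to 0.0860 without young ZT14 replicate 1, and the adjusted p over 40 lists was 0.0796, so the difference itself may be due to the spread between libraries. RNA quality was not measured apart from these values.

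The splits, and the shuffles of times below, argue against chance only if replicates are separate animals, which the labels do not say. For the age counts, 1 of 100 splits of the ages within times, the real one, gave as many as 201 genes. The highest other gave 5. For genes higher in old it was 1 of 100 (140 against 4), and for genes lower in old 1 of 100 (61 against 4). With times shuffled within an age, 1 of 100 splits gave as many rhythmic genes in young (1316 against 125) and 1 of 100 in old (1098 against 2). Chance could not be excluded for the 2 genes whose age difference varied over times, since 54 of 100 splits gave as many and the highest other gave 98. For rhythm differences the splits say nothing about chance: the real split gave 0 genes by limma (429 at an unadjusted p under 0.05), so 100 of 100 splits necessarily gave as many. The median of the other splits was 0 genes for rhythm differences and 2 for variation over times. The highest, 949 and 98, point to a structure of the samples in those splits, which was not tested.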

How the results depend on the processing

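Of the alternatives given here, those added after seeing the data are the fits without ZT10, without a pair of libraries, without all libraries of a replicate number, and the exact permutation of list means. Of 2234 values of named genes under alternatives, 2068 kept their direction and their side of the threshold, 131 lost it, 8 gained it and 27 changed sign. These include the genes named for rhythm differences, which did not pass in the reported fit. Such genes count as kept where they stay below the threshold in the same direction. Of 628 values for the 18 called lists under alternatives, 537 kept their call, 91 lost it and 0 changed camera's direction. That direction is relative to other genes. The mean of the unfolded protein response itself went from -0.07 to 0.03 with the deposited TPM unscaled, and its call was kept. Of the 20 named age genes, 16 to 20 stayed past the threshold under the other scalings, pseudocounts, filters, weights, robust fit and block, and 17 to 19 without any 1 library. In simulated data a planted rhythm difference of log2 1 was called in 12% of genes. How depth limits the calls was not tested. The cause was not tested for any value below, except where fewer genes or libraries entered.

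With the deposited TPM unscaled, 225 genes were higher and 38 lower in old (173 shared with the 201 reported), 1 gene differed at ZT6, 13 at ZT14 and 3 at ZT22, the median peak difference was 0.413 h, and the amplitude differences of Ssrp1 and Nnmt turned to 0.279 and 0.149. With the deposited FPKM, 222 genes were higher (187 of the 201 shared), 3 differed at ZT6 and Ssrp1 turned to 0.144. Quantile normalization gave 1 gene with a difference that varied over times, 2 at ZT22, 2 with a rhythm difference and 0.0137 for Ssrp1. A pseudocount of 0.1 gave 1 gene with a difference that varied over times and 1 at ZT18. No filter gave 17 that varied over times, 18 at ZT6, 18 at ZT14, 9 at ZT18 and 6 at ZT22. The filter at 5 TPM, with fewer genes tested, gave 68 higher, 0 that varied over times, 3 at ZT14, 0 at ZT18, 0 at ZT22 and 1 with a rhythm difference. Library weights (arrayWeights) gave 5 genes at ZT2, 2 at ZT6, 0 at ZT14, 2216 rhythmic in young, a median amplitude difference of -0.108 and 0.0161 for Ssrp1. Robust empirical Bayes gave 1 gene at ZT6. A 1.5-fold threshold as well left 34 lower genes. Adding a 12 h harmonic gave 3 genes with a rhythm difference. The F test over the 6 times gave 841 rhythmic genes in young and 693 in old, and the separate fit for each age 793 in young. Among genes rhythmic in young the median amplitude difference was -0.211. Camera with an estimated correlation called 3 lists and the exact permutation of list scores 10.

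Without ZT10 there were 70 genes higher in old, 631 rhythmic in young, 562 in old and 1 with a rhythm difference, from 20 libraries. With the 2 libraries that stand apart left out, 4 genes had a rhythm difference.

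Leaving out libraries gave these ranges: 27 to 150 higher, 5 to 85 lower, 0 to 36 that varied over times, 0 to 6 at ZT2, 0 to 27 at ZT6, 6 to 64 at ZT10, 0 to 53 at ZT14, 2 to 36 at ZT18 and 1 to 6 at ZT22. For rhythms the ranges were 74 to 1672 in young, 62 to 1137 in old and 0 to 3 for the difference, with a median amplitude difference of -0.125 to 0.0523 and amplitude differences of -0.0924 to 0.0443 for Slc25a20 and -0.136 to 0.132 for Ssrp1. The lowest counts came without all libraries of a replicate number: without replicate 1, 58 higher, 24 lower, 74 rhythmic in young and 135 in old, and without replicate 2, 27, 5, 84 and 62. Those age counts came from a model of age plus time, since each group then held 1 library, so they differ from the reported fit in model as well as in libraries. A single library left out gave 107 to 150 higher and 47 to 85 lower, with 151 to 177 of the 201 genes shared. At ZT10, 10 and 6 genes were called without young ZT10 replicates 1 and 2, and 30 and 25 without old ZT10 replicates 1 and 2. At ZT14, 53 genes were called without old ZT14 replicate 2 and 0 without replicate 1, 3 and 1 without young ZT14 replicates 1 and 2, 1 without either young ZT2 library and 8 without old ZT2 replicate 2. At ZT18, 36 and 5 were called without young ZT18 replicates 1 and 2, 10 without old ZT18 replicate 1 and 5 without either old ZT2 library. At ZT6, 27 and 2 were called without old ZT6 replicates 1 and 2, 4 and 3 without young ZT6 replicates 1 and 2, 5 without either old ZT2 library and 1 without either young ZT22 library. At ZT2, 6 were called without old ZT2 replicate 2, 1 and 2 without young ZT2 replicates 1 and 2, and 2 without either old ZT10 library. At ZT22, 6 and 4 were called without old ZT22 replicates 1 and 2, and 2 without either library of young ZT6, young ZT22 or old ZT14. The count that varied over times was 36 without young ZT18 replicate 1, 20 without old ZT14 replicate 2, 15 without old ZT6 replicate 1, 7 without old ZT22 replicate 1, 6 without old ZT2 replicate 2 and 0 without old ZT18 replicate 2. A rhythm difference was called in 3 genes without old ZT14 replicate 1, 2 without old ZT2 replicate 2, and 1 without young ZT6, ZT10 or ZT18 replicate 2 or old ZT2 replicate 1. With a single library left out, the group left with 1 library was assumed to vary like the others. The ranges given here cover the fits without a single library or without a replicate number. They leave out the fits without ZT10 and without the pair of libraries that stand apart.

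Blocking on the replicate number gave 220 higher and 133 lower genes (all 201 shared), 2 at ZT2, 140 at ZT10, 8 at ZT14 and 5 at ZT18. The first principal component (17.4% of the variance) was higher in replicate 2 in 11 of 12 groups, and deviations from group means correlated over 0.1 in 52 of 66 pairs of groups (median 0.186). Among the 6 pairs of young and old groups at the same time, 5 correlated over 0.1, and ZT10 did not (-0.108). The labels do not say what the number marks.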

Other observations

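The tests of gene position and of libraries given here were chosen only after the results were seen. Genes that differed with age clustered at 4 places among 1189 bins of the genome. Beside the chromosome 4 block (7 of 23 tested genes in its bin higher, Fisher adjusted p = 8.86e-06), 5 of 15 genes between 114000001 and 116000000 of chromosome 4, where the Cyp4a genes lie, were lower in old (Fisher adjusted p = 8.86e-06). On chromosome 12, 5 of 22 genes in the bin of the antibody heavy chain constant regions were higher (Fisher adjusted p = 0.00323), and on chromosome 19, 3 of 16 genes in the bin of the Cyp2c family were lower (Fisher adjusted p = 0.0373). Fisher's test treats genes as independent. Whether related genes share reads was tested only for the block of predicted genes, not for the Cyp4a, antibody or Cyp2c bins.

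Metallothioneins, small metal-binding proteins, peaked with the acute phase transcripts in old ZT10. Mt1 was at 2605.5 and 655.6 scaled TPM in the libraries of old ZT10 and at 97.4 or less in the others, and Mt2 was at 2522.0 and 747.4 in old ZT10. Saa1 reached 8089.4 and 1326.4 in old ZT10, 1205.1 and 705.1 in old ZT6 and 2577.6 in replicate 1 of old ZT2. Lcn2 was at 672 and 249.9 in old ZT10 and at 123 and 139.5 in old ZT6. Cd5l, a protein secreted by macrophages, was at 185.5 and 282 in old ZT10. Some major urinary protein genes were uneven between libraries: Mup11 averaged 740.2 ± 1034.5 in young and 37.7 in old, with 5 young libraries between 624 and 2728, which cannot be read as age differences since near-identical genes share reads.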
